A study of Mus musculus with 4 samples.

How the data were processed

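Single-cell RNA-seq was analysed from 4 kidney libraries of C57BL/6 wild-type mice, 2 healthy and 2 with MPO-AAGN, grouped and numbered by their titles. Although the series title speaks of patients, all samples are labelled as mouse. Per the labels' protocols, kidneys were digested with collagenase D and DNase I for 30 minutes, red cells were lysed with ammonium chloride, the suspension passed a 40 µm filter and a dead-cell removal kit, and 3' libraries were made on the 10x Genomics platform. Per the submitters' processing notes, Cell Ranger 3.1.0 and the genome build mm10 were used. The deposited matrices hold counts, whole numbers of UMIs per gene and barcode with no normalization, restricted by the authors to barcodes called as cells; the lowest total of any barcode was 500 UMIs. Barcode calling settings and the gene annotation are not given in the sources used here. Reads from near-identical copies of a gene can be lost or shared at this step, and how multi-mapped reads were treated is not given either.

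Barcodes with at least 500 UMIs, at least 250 genes and at most 50% of UMIs from mitochondrially encoded genes were kept. The gene minimum removed 101, 347, 385 and 1005 barcodes in healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2, and the mitochondrial limit 395, 549, 145 and 215. The barcodes with the highest Scrublet doublet scores (in scanpy 1.11.5) were then removed as a share of 0.8% per 1000 barcodes, which came to 5.81%, 8.57%, 4.24% and 5.46%, or 420, 937, 223 and 337 barcodes. Scrublet's automatic threshold marked 3, 305, 0 and 139 and so did not work in healthy 1 and MPO-AAGN 1. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 were used, with no integration across libraries. A cluster was named from marker genes fixed before the data were examined when at least 3 markers of the class were detected and at least 3 were among its 50 leading genes by fold, with no other class having more markers among its 10 leading genes. A cluster with 5 or more markers of another class among these 50 was split once at resolution 0.5, and leukocyte subsets were found by clustering again with 1000 variable genes and 15 components at resolution 1. A subset also had to have its first-listed marker in at least 10% of the cluster's cells and above its mean in the other clusters, and 1 marker or more among the 10 leading genes. These conditions and the thresholds on numbers of markers were set after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

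Cells are not replicates, so UMIs were summed per library and class. Sums ranged from 6942110 to 34575000 UMIs per library in proximal tubule cells and from 209808 to 5544350 in the other 6 classes tested. Genes were tested in classes with at least 50 cells in each of the 4 libraries with edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr by group, quasi-likelihood F test, Benjamini-Hochberg adjustment within a class and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F and is approximate. Shares of cells were tested by the same quasi-likelihood test on cell counts, with the log of the library's cells as an offset and without TMM, for classes with at least 10 cells in at least 2 libraries; subsets were tested over the leukocytes. The difference of a change between proximal tubule and endothelial cells was tested as an interaction with the library as a block. Of 23 gene lists fixed before the data were examined, 21 were tested as sets by camera (limma 3.58.1) with a preset correlation of 0.01 where at least 5 members were measured, with adjustment over all pairs of list and class; camera with an estimated correlation and fry were run beside it. The fixed panel of 24 genes was followed gene by gene. Exact permutation of 2 libraries against 2 allows no two-sided p below 0.333.

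Genes were named by a rule fixed before the data were examined: an adjusted p under 0.05, both libraries of a group above both of the other, a mean of at least 20 CPM in the higher group, and a mean CPM in the class of at least 0.1 times that of the gene's highest class, a guard against free RNA. The 10 largest changes per direction were taken in proximal tubule cells, endothelial cells and mononuclear phagocytes and the 5 largest elsewhere, leaving out immunoglobulin and T cell receptor variable segments, Xist, Y-linked genes, pseudogenes and predicted genes. Up to 4 members of each list that passed, by smallest p, and all panel genes tested were added without that guard, so a gene described as far below its highest class did not meet it. Some genes that meet the rule are not reported here, and the counts of named genes and of list members include them. CPM, a gene's UMIs scaled to a fixed total per sum, were computed from these counts. The CPM printed for genes in a class are scaled with TMM, and those behind shares of cells and free RNA are not. The level that free proximal tubule RNA alone would give was estimated from the proximal tubule genes found in a class, scaled to the proximal tubule profile of the same library. This takes all transcripts of these genes in the class as free RNA. Genes used for the scaling therefore come out near their measured level on average, whatever put them there. For them the estimate cannot tell free RNA from doublets or own expression. To compare shares of cells with a UMI across depths, cells were thinned to 1000 UMIs. Intervals are exact 95% binomial (Clopper-Pearson) intervals, and a count of 0 allows up to 3 counts; both cover counting error only.

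On counts simulated from these libraries with 100 genes changed 2-fold and 100 changed 4-fold, the test found 57% and 88% of them in proximal tubule cells, 14% and 89% in endothelial cells, 11% and 79% in mononuclear phagocytes, 19% and 93% in T cells, 28% and 79% in NK cells, 37% and 89% in intercalated cells, 28% and 91% in distal cells and 2% and 34% in the whole suspension. The interaction test, run on 8938 genes, found 11% and 62%, and 6 of its 79 calls (7.59%) were false, above the threshold of 0.05. The simulated spread was equal in both groups and followed the trend over expression, or 1 common value per class for the interaction. In the data the SD of the difference between replicates was 0.33 in healthy and 0.67 in MPO-AAGN proximal tubule cells. In distal cells it was 0.53 and 0.51. Recovery in the data can therefore be lower than simulated. The test of shares found 75% of 4-fold and 96% of 8-fold changes at a simulated dispersion of 0.1. These 2 values hold for that spread only, so a class that did not pass is not shown to be unchanged. Replicates were compared by chi-square over genes: in the proximal tubule the statistic per degree of freedom was 12.7 between the healthy libraries and 27.3 between the MPO-AAGN libraries, so the libraries of a group differed by more than counting error.

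Alternatives chosen before the data were examined were leaving out each library, the replicate number as a block, no doublet removal, Scrublet's automatic threshold, a mitochondrial limit of 25%, a minimum of 1000 UMIs, resolutions 0.5 and 2, libraries clustered separately, TMM of the class counts and a total without proximal tubule cells for shares, DESeq2 1.42.0, its size factors (RLE) in edgeR, no expression filter beyond 1 count, the guard against free RNA, equal cells per library, mitochondrially encoded genes left out, and the estimated correlation and fry for lists. Where a library is left out, the single library of its group is assumed to vary like the other group's. The alternatives of the same cells and UMIs in all 7 classes and of subsets named without their first-listed marker were chosen after the data were seen. Positions and Ensembl identifiers come from GENCODE vM21 on GRCm38, which is the mm10 assembly; all 203 named genes and 31011 of 31053 features (99.9%) had one. Xist and Y-linked genes were left out of naming. Immunoglobulin UMIs and cells of the classes with fewer than 50 cells in a library were not tested for gene changes.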

Results

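Kidneys of C57BL/6 wild-type mice were dissociated and their cells sequenced in droplets, with 2 libraries from healthy mice and 2 from mice with an experimental glomerulonephritis directed at myeloperoxidase (MPO-AAGN). Myeloperoxidase is a granule enzyme of neutrophils and a target of anti-neutrophil cytoplasmic antibodies (ANCA). Per the labels, the diseased mice were immunised under the skin with 20 µg of recombinant myeloperoxidase in Freund's complete adjuvant and again 7 days later in incomplete adjuvant. A further 7 days on, they received 1.5 mg of sheep globulin against the mouse glomerular basement membrane into a vein on 2 consecutive days, and they were killed 4 days after it. Healthy mice were not treated, so the contrast between the groups combines immunisation, adjuvant and globulin. The comparison asks which kidney and immune cells, and which of their transcripts, differ between the diseased and the healthy kidney. The deposited matrices held 7259 and 10712 barcodes in healthy 1 and healthy 2, with 33855300 and 51543561 unique molecular identifiers (UMIs). MPO-AAGN 1 and MPO-AAGN 2 held 5304 and 6820 barcodes with 30212757 and 26231674 UMIs. Nothing in the labels says that the 2 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The labels give no batch or date either. A difference in preparation or run between the groups therefore cannot be told apart from disease. Below, means are ± SD over the 2 libraries of a group (n = 2), log2 fold changes are MPO-AAGN over healthy ± SE, and gene levels are CPM within the class.

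After filtering, 6343, 8879, 4551 and 5263 cells remained in healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2, with medians of 2701, 3143, 4077 and 2789 UMIs per cell. Cells were named from marker genes, and each name stands for cells that resemble that type by these markers. Proximal tubule cells were the largest class in 3 libraries, at 61.5%, 64.6% and 51.8% of cells in healthy 1, healthy 2 and MPO-AAGN 2. In MPO-AAGN 1 they made up 21.0% and T cells 24.2%. Leukocytes together made up 13.1%, 14.6%, 54.2% and 13.4% of cells in the same order of libraries (13.8% ± 1.10 against 33.8% ± 28.8, two-sided exact permutation p = 0.667, where 2 libraries against 2 allow no p below 0.333). Unnamed clusters held 0.221%, 0.146%, 1.05% and 0.418% of cells.

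Neutrophils, the phagocytes that carry myeloperoxidase, were more frequent in MPO-AAGN kidneys, at 9.80% and 0.874% of cells (446 and 46 cells) against 0.142% and 0.0676% (9 and 6 cells) in healthy kidneys. Their share rose 50.7-fold (log2 fold change 5.66 ± 1.29, adjusted p = 0.00852, higher in both MPO-AAGN libraries than in both healthy ones, exact permutation p = 0.333). A cluster of 95 of these cells, all from MPO-AAGN 1, had a median of 693 UMIs, close to the minimum of 500 UMIs, which can remove neutrophils. The share passed no more without healthy 1 (adjusted p = 0.191) or healthy 2 (0.339), or with finer clusters at resolution 2 (0.080), and could not be tested without either MPO-AAGN library. No other of the 16 tested classes passed. Thick ascending limb cells were 0.709% and 0.664% of cells in healthy libraries and 5.54% and 2.51% in MPO-AAGN libraries (2.55 ± 0.93, adjusted p = 0.118). Podocytes, the filtering epithelium of the glomerulus, were 0.0473% and 0.0451% against 0.264% and 0.228% (2.36 ± 1.01, 0.179), and mononuclear phagocytes 2.29% and 1.87% against 12.8% and 2.53% (1.88 ± 0.97, 0.286). T cells were 5.66% and 6.89% against 24.2% and 7.28% (1.33 ± 0.91, 0.444), and B cells 3.07% and 3.50% against 1.85% and 0.665% (-1.39 ± 0.91, 0.444). Proximal tubule cells were lower in both MPO-AAGN libraries (-0.79 ± 0.88, 0.555). Mast cells or basophils numbered 5, 10, 0 and 0 and were too few to test. A count of 0 allows up to 0.0659% and 0.0570% of cells in the MPO-AAGN libraries. The number of classes that passed was 0 without healthy 1, 0 without healthy 2, 5 without MPO-AAGN 1 and 3 without MPO-AAGN 2. Collagenase digestion for 30 minutes, red cell lysis, a 40 µm filter and a dead-cell removal kit preceded loading, and each can set how many cells of a class are recovered.

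**Figure D1:**
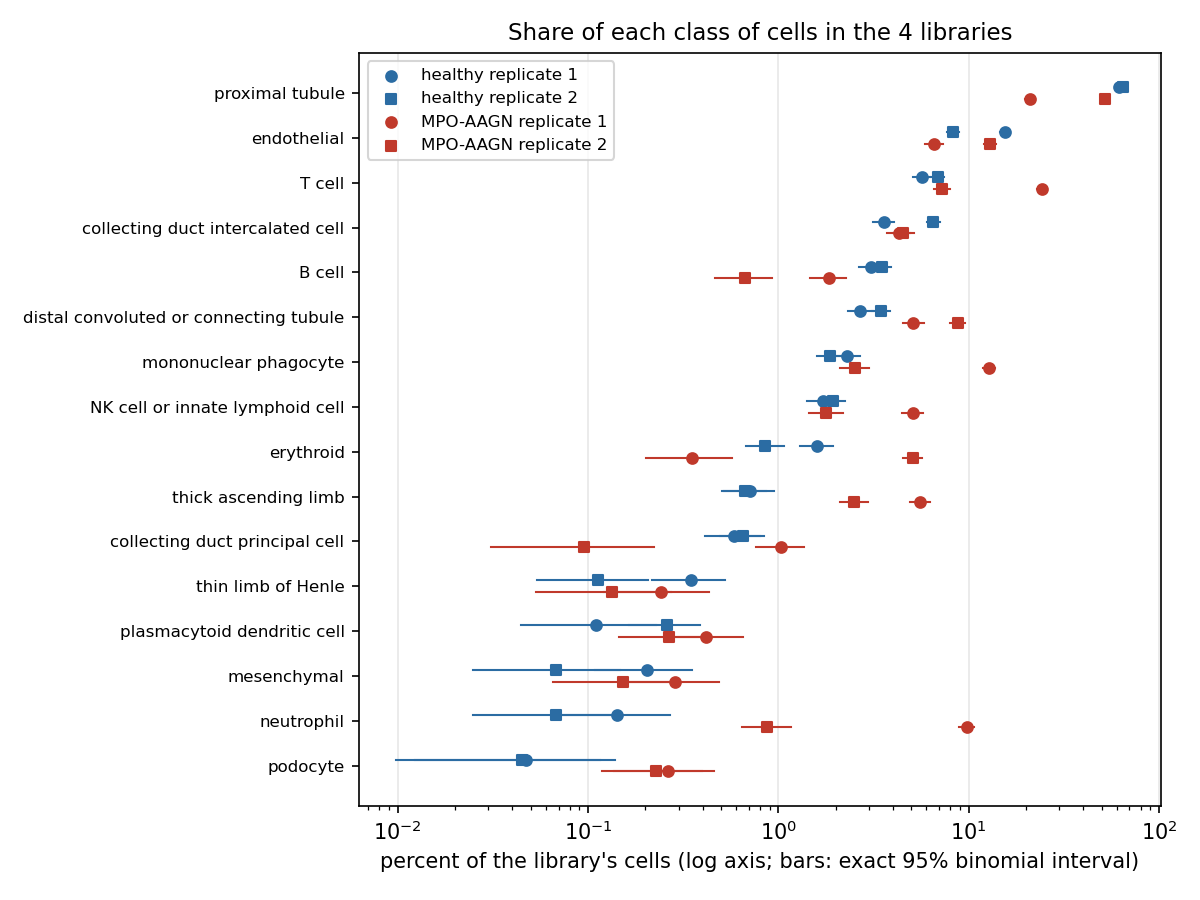
Share of each class among the cells of a library, in percent on a log axis, for healthy (blue) and MPO-AAGN (red) libraries, with replicate 1 as circles and replicate 2 as squares; bars are exact 95% binomial intervals, which cover counting error only. Neutrophils lie at 0.142% and 0.0676% in healthy libraries and at 9.80% and 0.874% in MPO-AAGN libraries, and many classes differ more between the MPO-AAGN libraries than between the healthy ones.

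Among leukocytes, type 1 conventional dendritic cells, which present antigen to CD8 T cells, were 2.41% and 2.54% in healthy libraries and 0.730% and 0% in MPO-AAGN libraries (log2 fold change -2.21 ± 0.57, adjusted p = 0.0134). MPO-AAGN 2 had 0 of 705 leukocytes of this kind, which allows a share of up to 0.426%. The subset is the single cluster m0, led by Cd7, Ifi205 and Xcr1, with 2 markers of another subset among its 10 leading genes. Cluster m9, led by Ccr7, Ifitm1 and Ccl17, stayed unnamed. It held 0.121% and 0.308% of leukocytes in healthy libraries and 3.20% and 0% in MPO-AAGN libraries. Whether it holds dendritic cells was not tested. The call was lost without healthy 1 (adjusted p = 0.174), healthy 2 (0.235) or doublet removal (0.394), with Scrublet's automatic threshold (0.974, at a change of -0.0160) and at a minimum of 1000 UMIs (0.409). It was also lost at resolution 0.5 (0.659, at a change of -0.40) and 2 (0.205). Clusters m3, m12 and m13 had monocyte markers and are compared by number, since among the 10 leading genes of m13 neutrophil markers outnumbered monocyte markers (6 against 3). Cluster m3, led by Ly6c2, Gm9733 and Fn1, held 5.07% and 4.08% of leukocytes in healthy libraries and 0.0811% and 0.426% in MPO-AAGN libraries. Cluster m12, led by S100a8, Hp and Fn1, held 0% and 0.154% against 2.15% and 0%. Cluster m13, led by Chil3, Retnlg and S100a8, held 0% in both healthy libraries against 1.99% and 0.993%. A count of 0 allows up to 0.362% and 0.231% in the healthy libraries. Regulatory T cells were 1.93% and 1.46% against 3.73% and 3.12% (1.06 ± 0.48, 0.0814), and resident-type macrophages 7.84% and 5.00% against 9.08% and 14.0% (0.84 ± 0.39, 0.0814). Non-classical monocytes (0.91 ± 0.66, 0.197) did not pass, and the 30 gamma-delta or innate-like T cells were not tested. With subsets named without their first-listed marker, an alternative chosen after the data were seen, the dendritic cell call ended (0.156). Under it CD4 T cells, a name no cluster had otherwise, passed as lower in MPO-AAGN (-1.69 ± 0.13, adjusted p = 0.0075). Gamma-delta or innate-like T cells passed as higher (4.4 ± 0.62, 0.0241). They then numbered 434, of which 404 were cluster T9, unnamed in the main naming. No other subset passed under it, so these calls depend on the naming rule.

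Among the largest increases in proximal tubule cells of diseased kidneys were several genes of fatty acid metabolism. Cyp4a14, a fatty acid omega-hydroxylase, went from 0.893 ± 0.0964 to 1509.6 ± 433 CPM (log2 fold change 10.73 ± 0.33, adjusted p = 0.000615). Ucp2, an uncoupling protein of the inner mitochondrial membrane, rose 97.3-fold to 1191 ± 231 CPM, and Pdk4, which restrains pyruvate dehydrogenase, 37.2-fold to 488 ± 152 CPM. Cyp27b1, the enzyme that activates vitamin D, rose from 0.492 ± 0.263 to 66.6 ± 7.51 CPM (6.98 ± 0.31, 0.0012). Among the largest decreases was Odc1, the first enzyme of polyamine synthesis, from 1555 ± 143 to 217 ± 2.83 CPM (-2.84 ± 0.13, 0.0012). Another was Idi1, of isoprenoid and sterol synthesis, from 131 ± 6.65 to 12.8 ± 3.50 CPM (-3.38 ± 0.21, 0.00204). Of 12140 genes tested, 1467 rose and 1367 fell. The other named increases were Eif4ebp3 (5.44 ± 0.42), Cyp4a10 (5.26 ± 0.37), Fabp1 (4.84 ± 0.53), the glutamine transporter Slc38a3 (4.85 ± 0.32) and Sox9. The other named decreases were Smcp, Dleu7, Ppard, Bcl6, Hsd3b2, Itgb6, Car3 and Hsf2bp (log2 fold changes -3.60 for Smcp to -2.72 for Hsf2bp). Sox9, a transcription factor of injured tubules, passed with an adjusted p of 0.0489 from 0.0874, 0.118, 65.7 and 0.792 CPM in the 4 libraries, so MPO-AAGN 1 sets its fold, and without healthy 2 its adjusted p was 0.0989. Cyp4a14 and Cyp4a10, Hsd3b2 and Hsd3b3, and Acot1 and Acot2 have near-identical copies among which counting can split or drop reads, so their levels are uncertain.

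**Figure D2:**
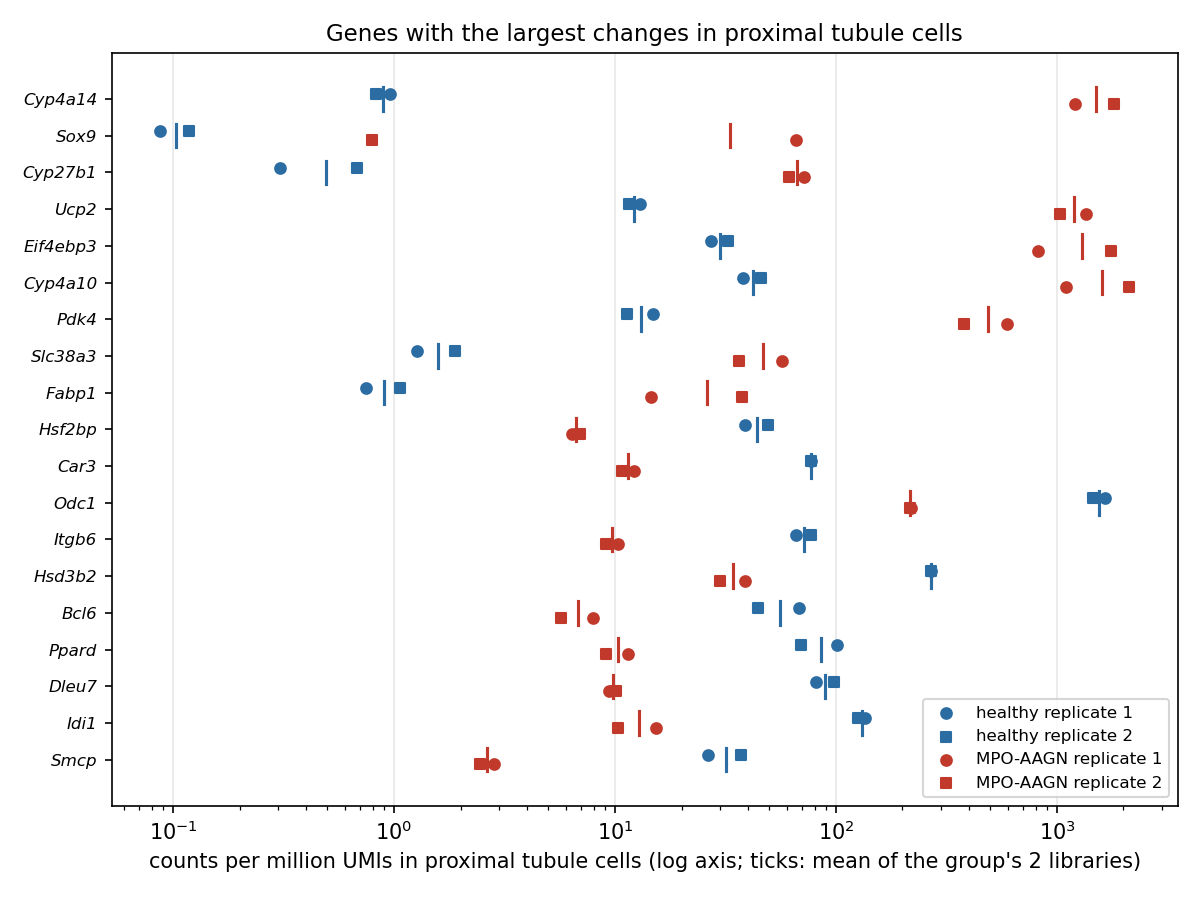
Level of genes with the largest named changes in proximal tubule cells, in CPM on a log axis, with each of the 4 libraries as a point and group means as ticks. Cyp4a14 lies near 1 CPM in healthy libraries and at a mean of 1509.6 CPM in MPO-AAGN libraries, Odc1 goes from a mean of 1555 to 217 CPM, and the MPO-AAGN libraries stand apart for Sox9 at 65.7 and 0.792 CPM.

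By fixed gene list, 22 of the 31 fatty acid oxidation genes rose in proximal tubule cells and 0 fell, by edgeR and as many adjusted over the list alone (list test adjusted p = 1.54e-26, adjusted p = 0.839 with an estimated correlation). They included Cyp4a14, Pdk4, Acot1 (2.80 ± 0.12) and Acot2 (2.42 ± 0.13). Of 29 tubular injury genes 16 rose and 0 fell (21 and 0 adjusted over the list alone, 5.49e-11). Among them were Fga, the fibrinogen alpha chain, from 10.3 ± 4.02 to 217 ± 21.8 CPM, Myc (2.68 ± 0.19), the stress cytokine Gdf15 (1.55 ± 0.15) and Sox4 (2.85 ± 0.32, far below its level in another class). The dissociation and immediate early list had 21 of 39 genes up and 2 down (24 and 4 adjusted over the list alone, 7.26e-07), led by Myc, Ier3, Egr1 and Zfp36, the last 3 far below their highest class. Of 13 mitochondrially encoded genes 9 rose and 0 fell (11 and 0, 0.00251), among them mt-Nd1 by 0.79 ± 0.12. The median share of mitochondrial UMIs per cell, over the cells of all classes, was 2.32%, 2.46%, 2.63% and 3.42% in healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2. Complement genes had 3 of 14 up (6 adjusted over the list alone, 0.00862), namely C3 (3.58 ± 0.44), C2 (1.17 ± 0.21) and Cd46 (2.85 ± 0.66), of which C3 and Cd46 lie far below their highest class. Glycolysis and hypoxia genes had 6 of 22 up and 1 down (10 and 1, 0.0242), with Eno1 (1.13 ± 0.18), Egln3 (1.11 ± 0.18) and Adm (2.06 ± 0.24) up and Tpi1 (-0.61 ± 0.11) down. For each of these 5 lists the adjusted p was 0.839 with an estimated correlation. Proximal tubule transport genes, which include class markers such as Slc4a4 and Slc13a1, had 13 of 34 up and 3 down (17 and 3 adjusted over the list alone, 0.00146), with the fructose transporter Slc2a5 (2.97 ± 0.17) and the glucose transporter Slc5a1 (1.94 ± 0.15) among them. Ribosomal protein genes had 7 of 38 down and 0 up (0 and 0 adjusted over the list alone, 0.00694), such as Rpl8 (-0.49 ± 0.11). For these last 2 lists the adjusted p was 0.906 with an estimated correlation.

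In the proximal tubule, 434 of the genes that rose and 55 of those that fell lay below 0.1 times their level in the highest class, which leaves 2345. Among the genes below that level were the adhesion receptor Icam1 (2.91 ± 0.59) and Spp1, the matrix protein osteopontin. Spp1 stood at 42.0, 39.7, 1591 and 117.5 CPM in healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2. Clusters 0, 2, 3, 5, 13, 15 and 21 held 94.6% and 94.4% of healthy proximal tubule cells and 10.2% and 9.79% of those in MPO-AAGN, while clusters 6, 27 and 28 held 0.718% and 0.732% against 88.1% and 85.0%. Libraries were clustered without integration, and whether preparation or batch adds to this split was not tested. The count of 2834 genes became 834 without healthy 1, 382 without healthy 2, 4716 without MPO-AAGN 1 and 5352 without MPO-AAGN 2. Of the 51 named calls 12 were lost without healthy 1 (adjusted p of 0.0582 to 0.330) and 16 without healthy 2 (0.0595 to 0.393), among them mt-Nd1, Rpl8, Tpi1, Egln3, C2 and Cd46 in both, and Eno1, Spp1 and Sox9 without healthy 2. List calls were lost for ribosomal (adjusted p = 0.0525) and complement genes (0.105) without MPO-AAGN 1, and for glycolysis without MPO-AAGN 1 (0.0900) or MPO-AAGN 2 (0.0570). Keeping only genes near their highest class ended the calls of the dissociation (0.834) and glycolysis lists (0.175).

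Endothelial cells of diseased kidneys showed more Lrg1, a secreted glycoprotein that promotes vessel growth, from 9.53 ± 4.38 to 399 ± 364 CPM (log2 fold change 5.41 ± 0.73, adjusted p = 0.00749). Ddit4, an inhibitor of mTORC1, rose from 26.2 ± 10.9 to 837 ± 428 CPM (4.96 ± 0.47, 0.00212) and Fkbp5, a co-chaperone of the glucocorticoid receptor, from 26.4 ± 14.7 to 360.3 ± 14.1 CPM (3.73 ± 0.37, 0.00212). Cdkn1a, a cell cycle inhibitor, rose 6.86-fold, and Cyp26b1, which degrades retinoic acid, 12.1-fold. Esm1, a proteoglycan of activated endothelium, fell from 1292 ± 101 to 411 ± 100.4 CPM (-1.65 ± 0.30, 0.0237), and the basement membrane collagen Col15a1 from 172 ± 32.7 to 25.9 ± 11.2 CPM (-2.77 ± 0.34, 0.00478). Of 9587 genes 150 rose and 83 fell, of which 20 and 4 lay below 0.1 times their level in the highest class. Zbtb16 (4.55 ± 0.43), Map3k6, Bc1, Col13a1 and Slc10a6 were other large increases, and Rflna, Olfml2b, Tiam1, Idi1, Slc7a13, Hsd3b2, Defb29 and Car3 other large decreases. Pdk4, Cyp4a10 and Cyp4a14 stood below what free proximal tubule RNA alone would give, estimated at 134% to 164% of the Pdk4 level. The same estimate was over 50% for Slc7a13, Hsd3b2 and Defb29 in healthy libraries. It counts all transcripts of the proximal tubule gene set in the class as free RNA, so it cannot show their source. Icam1 (0.81 ± 0.31, 0.229) and Vcam1 (0.90 ± 0.32, 0.197), adhesion molecules for leukocytes, did not pass.

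The endothelial activation and coagulation list rose, with 3 of 24 genes up and 1 down (7 and 3 adjusted over the list alone, list test adjusted p = 0.00349, adjusted p = 0.839 with an estimated correlation). Lrg1, Angpt2 (1.78 ± 0.37), a destabiliser of vessels, and Thbs1 (2.72 ± 0.38, far below its highest class) were up and Esm1 was down. Hemoglobin genes, transcripts of red cells, had 4 of 5 up (5 adjusted over the list alone, 5.49e-11). Complement genes had 1 of 5 up, the membrane inhibitor Cd59a at 2.08 ± 0.29 (1 adjusted over the list alone, 0.0372). Both lists had an adjusted p = 0.839 with an estimated correlation. Hemoglobin made up 0.977%, 0.545%, 0.442% and 4.73% of the UMIs in cells of healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2, and Hba-a1 and Hba-a2 are near-identical. Tubular injury genes had 3 of 20 up, Cdkn1a, Lcn2 and Cd14, the last 2 far below their highest class (4 adjusted over the list alone, 0.00131, adjusted p = 0.872 with an estimated correlation). Fatty acid oxidation genes had 4 of 30 up (8 adjusted over the list alone, 0.00694), among them Pdk4, Cyp4a10 and Cyp4a14, and dissociation genes 2 of 38, Cebpb and Cebpd (3 adjusted over the list alone, 0.0126). Transport genes of the proximal tubule fell as a list, with 1 of 26 up, Abcg2 (1.68 ± 0.26), and 1 down, Slc7a13 (1 and 4 adjusted over the list alone, 0.000284). For these last 3 lists the adjusted p was 0.906 with an estimated correlation. Transcripts of 149 proximal tubule genes were 3.48%, 3.20%, 0.947% and 2.68% of the UMIs in endothelial cells of healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2.

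Cluster 19 held 99.9% of the endothelial cells in both healthy libraries and 9.63% and 10.1% in MPO-AAGN libraries, and cluster 20 held 90.4% and 89.9% of those. As in the proximal tubule, this split can hold differences of preparation or batch as well as of disease. The 233 genes became 119 without healthy 1, 126 without healthy 2, 1332 without MPO-AAGN 1 and 2110 without MPO-AAGN 2. Esm1 lost its call without healthy 1 (adjusted p = 0.262) or healthy 2 (0.152), as did Abcg2 (0.293 and 0.263), Cebpd (0.0513 and 0.0615) and Cd59a (0.0761 and 0.0622). Defb29 (0.101) and Car3 (0.0775) lost it without healthy 1, Angpt2 (0.119) and Hba-a2 (0.0615) without healthy 2 and Cyp4a10 (0.127) without MPO-AAGN 2. Without MPO-AAGN 1 the list calls ended for transport (0.934), injury (0.273), dissociation (0.0953, with the direction turned) and complement (0.249), and without MPO-AAGN 2 that for fatty acid oxidation (0.468, direction turned). Keeping only genes near their highest class ended the injury (0.0854), fatty acid oxidation (0.0985) and dissociation calls (0.102).

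Between proximal tubule and endothelial cells, the change itself differed for 277 of 12543 genes by an interaction test with the library as a block, 183 with a larger and 94 with a smaller log2 change in the proximal tubule. Of the 277 genes, 146 reached 0.1 times their level in the highest class in both classes. Ucp2 rose in both, by 6.60 in the proximal tubule and 3.06 in endothelial cells (difference 3.50 ± 0.34, adjusted p = 5.94e-05), and Fkbp5 rose less in the proximal tubule, by 1.17 against 3.73 (difference -2.67 ± 0.36, 0.000771). Ppard, a nuclear receptor for fatty acids, fell by 3.07 in the proximal tubule, beside -0.91 in endothelial cells, which did not pass there (difference -2.25 ± 0.44, 0.0117). The repressor Bcl6 was at -3.07 against -0.86 (difference -2.31 ± 0.54, 0.0376), Acot2 at 2.42 against 0.52 (1.84 ± 0.39, 0.0226) and Egln3, an oxygen sensor, at 1.11 against -0.93 (1.99 ± 0.34, 0.0053). Of the 174 genes with opposite fitted directions, 2 were called in both classes, named here after their values were seen. Il15, a cytokine that sustains NK and CD8 T cells, fell by 1.45 in the proximal tubule and rose by 1.95 in endothelial cells (difference -3.46 ± 0.33, 4.92e-05). Sipa1l2 was at 2.72, far below its highest class, and -1.23 (3.90 ± 0.37, 4.92e-05). The count was 109 without healthy 1, 83 without healthy 2, 868 without MPO-AAGN 1 and 2187 without MPO-AAGN 2. Bcl6 (adjusted p = 0.0796 and 0.177) and Acot2 (0.0512 and 0.384) lost their calls without healthy 1 or healthy 2, Egln3 without healthy 2 (0.153) and Ppard without MPO-AAGN 2 (0.101).

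Cells of the distal convoluted or connecting tubule carried more immediate early transcripts in disease. Fos rose from 211 ± 13 to 1629 ± 135 CPM (log2 fold change 2.95 ± 0.17, adjusted p = 3.11e-08) and Junb from 124.8 ± 64.2 to 1139 ± 100.8 CPM (3.24 ± 0.26, 5.46e-07). Spp1 rose 5.01-fold to 6300 ± 4079 CPM (8.1e-05), and Angptl4, an inhibitor of lipoprotein lipase, from 7.97 ± 7.87 to 135 ± 1.32 CPM (4.29 ± 0.41, 4.03e-06). Lcn2, which binds iron-carrying siderophores, was at 0 UMIs in both healthy libraries and at 456 and 37.8 CPM in MPO-AAGN, at least 52.5-fold higher against a floor of 3 counts per library, though far below its level in its highest class. Of 9022 genes 236 rose and 332 fell, of which 27 and 132 lay below 0.1 times their level in the highest class. Bc1, Lpo, Cebpd (4.78 ± 0.64) and Angptl4 were among the largest named increases. The dissociation and immediate early list had 23 of 38 genes up and 0 down (28 and 2 adjusted over the list alone, 2.38e-38). Tubular injury genes had 7 of 20 up, among them Cdkn1a (2.49 ± 0.32) and Klf6 (1.88 ± 0.19) (12 and 2, 6.95e-08). For both lists the adjusted p was 0.839 with an estimated correlation. Fatty acid oxidation genes had 11 of 30 up and 4 down (14 and 4 adjusted over the list alone, 8.83e-05, adjusted p = 0.866 with an estimated correlation), with Pdk4 at 3.26 ± 0.24 and Acot1 at 2.56 ± 0.27 up and Acsm2 down. Ribosomal protein genes fell as a list with 0 of 38 called either way (0 adjusted over the list alone, 0.0138, adjusted p = 0.906 with an estimated correlation).

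Proximal tubule transport genes had 15 of 25 down and 0 up in the same distal cells (0 up and 19 down adjusted over the list alone, 9.97e-21, adjusted p = 0.839 with an estimated correlation), such as Slc34a1 (-2.04 ± 0.26) and Lrp2 (-2.25 ± 0.33). Gatm fell from 333 ± 28.5 to 19.8 ± 4.72 CPM (-4.04 ± 0.24, 3.24e-08), next to Car3, Acmsd, Acsm1 and Gamt. For all 10 named decreases the level that free proximal tubule RNA alone would give exceeded 50% of the measured one in both healthy libraries. It also did in MPO-AAGN for the named increase Acot1 (63.7% and 69.9%). The estimate counts all transcripts of the proximal tubule gene set in the class as free RNA. High values for such genes are thus built in and do not show where the transcripts came from. Proximal tubule genes were 3.45%, 3.14%, 1.04% and 1.50% of the UMIs of this class in healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2. Clusters 18.0 and 18.1 held 87.7% and 86.0% of healthy cells and 7.30% and 7.17% of MPO-AAGN cells, which lay in 18.2 to 18.4. The 568 genes became 237 without healthy 1, 215 without healthy 2, 1077 without MPO-AAGN 1, 1204 without MPO-AAGN 2 and 256 by DESeq2. Acmsd (0.0997) and Gamt (0.0774) were lost without healthy 1, Acsm1 (0.203), Gamt (0.128) and Cxcl10 (0.0731) without healthy 2, and the list calls of fatty acid oxidation without MPO-AAGN 2 (0.105) and of ribosomal genes without healthy 2 (0.124) or MPO-AAGN 2 (0.0954). The transport call ended when only genes near their highest class were kept (0.369).

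Intercalated cells of the collecting duct, which move acid and base, had 44 of 8449 genes up and 57 down. Of these, 8 that rose and 27 that fell lay below 0.1 times their level in the highest class. Pigr, the receptor that carries polymeric immunoglobulin across epithelia, rose from 2.30 ± 0.759 to 53.2 ± 43.9 CPM (log2 fold change 4.39 ± 0.71, adjusted p = 0.0354) and Bc1 by 3.76 ± 0.72. Npl fell by 3.32 ± 0.43, Idi1 by 3.01 ± 0.36 and Ahsa2 by 2.03 ± 0.34. The unfolded protein response list fell, with 1 of 19 genes up and 3 down (2 and 9 adjusted over the list alone, 0.000294, adjusted p = 0.839 with an estimated correlation). The chaperone-related Sdf2l1 (-1.82 ± 0.33), Calr and Pdia6 were down and Herpud1 (1.85 ± 0.35), of protein degradation at the endoplasmic reticulum, was up. Fatty acid oxidation genes had 9 of 30 up and 0 down (17 and 2 adjusted over the list alone, 3.52e-21, adjusted p = 0.839 with an estimated correlation). Of these, for Pdk4, Acot1 and Cyp4a14 free proximal tubule RNA alone would give over 50% of the measured level (for Pdk4, 64.7% and 93.6%). The same estimate was over 50% of the healthy level for Gatm, Amacr and Slc7a13 among the decreases. Dissociation genes had 1 of 38 up, Cebpb (8 up and 2 down adjusted over the list alone, 0.008, adjusted p = 0.839 with an estimated correlation). Tubular injury genes had 1 of 14 up, Cdkn1a (6 adjusted over the list alone, 0.0165, adjusted p = 0.866 with an estimated correlation). Mitochondrially encoded genes rose as a list with 0 of 13 called (0 adjusted over the list alone, 0.00349), with the median mitochondrial share of UMIs per cell, over all classes, at 2.32% and 2.46% in healthy and 2.63% and 3.42% in MPO-AAGN libraries. Transport genes of the proximal tubule fell with 1 of 21 down, Slc7a13 (1 up and 2 down adjusted over the list alone, 0.0461). Both had an adjusted p = 0.906 with an estimated correlation. The 101 genes became 0 without healthy 1, 0 without healthy 2, 244 without MPO-AAGN 1 and 461 without MPO-AAGN 2. All 18 named calls were lost without either healthy library (adjusted p of 0.0617 to 0.570), Sdf2l1 also without MPO-AAGN 1 (0.069) and Bc1 without MPO-AAGN 2 (0.0517). The calls of the unfolded protein response list were lost without healthy 2 (0.0702) or MPO-AAGN 2 (0.0558), of mitochondrial genes likewise (0.160 and 0.459). The calls of dissociation genes were lost without healthy 1 (0.246), of injury genes without MPO-AAGN 1 (0.979, direction turned) and of transport genes without healthy 2 (0.158) or MPO-AAGN 1 (0.788, direction turned). Keeping only genes near their highest class ended those of dissociation (0.330) and injury (0.106).

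Mononuclear phagocytes, which take in monocytes, macrophages and dendritic cells, had 12 of 7151 genes up and 10 down. Of these, 1 that rose and 5 that fell lay below 0.1 times their level in the highest class. Prtn3, proteinase 3 of granulocyte granules and the other main target of ANCA, rose from 4.11 ± 0.204 to 131 ± 65.4 CPM (log2 fold change 5.05 ± 0.53, adjusted p = 0.0354). Apoe, a lipoprotein component and one of the markers of the resident macrophage subset, rose from 2047 ± 429 to 11126 ± 1930 CPM (2.44 ± 0.29, 0.0397). Next to it rose Ddit4 (4.70 ± 0.36), the NAD hydrolase Cd38 (4.30 ± 0.54), Fkbp5 (3.47 ± 0.36), Pla2g7, the acid phosphatase Acp5, the metallothionein Mt1, Dpep2 and the lysosomal protease Lgmn. Dpep2 is one of 71 symbols that name more than a single feature. Cxcl9, an interferon-induced chemokine for T cells, fell from 138 ± 42.6 to 5.12 ± 7.24 CPM (-4.02 ± 0.55, 0.0456), with Serpinb2 (-2.83 ± 0.39), the sterol synthesis gene Fdps (-2.53 ± 0.32) and Camkk2. The interferon response list fell, with 0 of 31 genes up and 1 down, Cxcl9 (0 and 8 adjusted over the list alone, 1.21e-07). So did the unfolded protein response with 0 of 19 called (0 up and 7 down, 6.51e-05) and the dissociation list with 0 of 40 called (1 up and 7 down, 0.00595). The neutrophil granule list rose with 2 of 20 up, Prtn3 and Lcn2, and 1 down, Cd177 (6 and 1 adjusted over the list alone, 6.51e-05). So did complement with 0 of 13 called (7 up and 1 down, 0.000103), extracellular matrix with 0 of 6 called (3 up, 0.0106) and tubular injury with 1 of 21 up, Lcn2 (7 up and 4 down, 0.0185). For these 7 lists the adjusted p was 0.839 with an estimated correlation. Cell cycle (0 of 26 called, 0.0185) and hemoglobin genes (0 of 5, 0.0367) rose and proximal tubule transport genes fell (0 of 11, 0.0126) as lists. Of these genes 0, 0 and 1 were called when adjusted over the list alone, and each list had an adjusted p = 0.906 with an estimated correlation.

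Clusters m0, m1 and m3 held 86.2% and 87.3% of healthy mononuclear phagocytes and 3.44% and 6.02% of those in MPO-AAGN. Cluster m13, with 49 and 7 cells of MPO-AAGN 1 and MPO-AAGN 2 and 0 of healthy libraries, had Prtn3, Lcn2 and the neutrophil markers S100a8 and Retnlg among its 10 leading genes within the class. Of all Mpo and Elane UMIs in MPO-AAGN 1, 396 of 649 and 504 of 917 lay in 12 and 10 of its 582 mononuclear phagocytes, and MPO-AAGN 2 had 2 Mpo UMIs and 1 Elane UMI in all. Both encode granule enzymes, and Mpo was followed because the mice were immunised against its product. Lcn2 and Cd177 lay far below their highest class, and Lcn2 was found in 94.4% and 95.7% of neutrophils of MPO-AAGN, at medians of 2771 and 3080 UMIs per cell, against 4.28% of proximal tubule cells of MPO-AAGN 1 at a median of 5254. The 22 genes became 77 without healthy 1, 76 without healthy 2, 737 without MPO-AAGN 1, 1660 without MPO-AAGN 2 and 91 by DESeq2. Lgmn (0.115 and 0.110) and Dpep2 (0.115 and 0.060) lost their calls without healthy 1 or healthy 2 and Apoe without healthy 1 (0.072). List calls were lost without healthy 1 for hemoglobin (0.160), without healthy 2 for dissociation (0.065), injury (0.0725) and cell cycle (0.065). They were also lost without MPO-AAGN 1 for dissociation (0.0526), transport (0.959) and cell cycle (0.909, direction turned), and without MPO-AAGN 2 for hemoglobin (0.605, direction turned). The injury list turned direction when only genes near their highest class were kept (0.959).

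T cells had 16 of 8997 genes up and 31 down. Of these, 2 that rose and 27 that fell lay below 0.1 times their level in the highest class. Tigit, an inhibitory receptor, rose from 31.5 ± 1.17 to 229 ± 48.2 CPM (log2 fold change 2.85 ± 0.23, adjusted p = 0.0183). A Tigit UMI was present in 6.96%, 5.56%, 40.3% and 32.4% of T cells in healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2. Thinned to 1000 UMIs per cell, leaving out 40, 52, 58 and 48 shallower cells, the shares were 3.13%, 1.79%, 15.8% and 21.8%. In proximal tubule cells they were 0.313% or less unthinned, and median depths were 2720, 2446, 4124 and 1945 UMIs in T cells and 3733, 4522.5, 5254 and 3634 in proximal tubule cells. AA467197 (5.60 ± 0.73), the interleukin 17 receptor subunit Il17re (3.98 ± 0.49), the apoptosis gene Bbc3, the leukotriene receptor Ltb4r1 and Il18r1 (1.59 ± 0.20) also rose. Klf2, which maintains naive T cell circulation, fell from 1770.3 ± 145 to 761 ± 73.3 CPM (-1.22 ± 0.14, 0.0334). With it fell the lymph node homing receptor Ccr7, a marker of the class (-1.24 ± 0.17), and Idi1 (-2.66 ± 0.33). The cytokine Il17a, at 3.80, 6.89, 199 and 8.25 CPM, did not pass (4.33 ± 1.23, 0.137), nor did Ifng (-0.11 ± 0.32, 0.900) or the checkpoint receptor Pdcd1 (1.79 ± 0.31, 0.0619). AA467197, Il17a and Il17re were among the 10 leading genes of cluster T9, and Il17a and Il17re among those of T11. Clusters T5, T9, T11 and T12 held 3.06% and 2.94% of healthy T cells and 69.6% and 69.7% of those in MPO-AAGN, where T0, T1 and T2 held 78.0% and 77.9% against 0.453% and 3.66%.

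The T cell effector and checkpoint list rose with 1 of 34 genes up, Tigit (7 up and 1 down adjusted over the list alone, 9.06e-05). Cell cycle genes also rose, with 0 of 33 called (7 up adjusted over the list alone, among those named Birc5 at 1.12 ± 0.25, 6.95e-08). So did inflammatory cytokines and receptors with 1 of 20 up, Il18r1 (6 adjusted over the list alone, 0.00196). The unfolded protein response list fell with 0 of 19 called (6 down adjusted over the list alone, 0.00694). Antioxidant genes fell too, with 1 of 19 up, Mt1, far below its highest class (1 up and 6 down adjusted over the list alone, 0.044). Proximal tubule transport genes fell, with 2 of 23 down, Slc7a13 and Slc17a3 (15 down adjusted over the list alone, 3.56e-13), where free proximal tubule RNA alone would give over 50% of the healthy level of both. For these 6 lists the adjusted p was 0.839 with an estimated correlation. The dissociation list fell with 1 of 38 down, Klf2 (6 adjusted over the list alone, 0.00486, adjusted p = 0.866 with an estimated correlation). Proximal tubule genes were 2.09%, 1.82%, 0.331% and 1.13% of T cell UMIs in healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2. The 47 genes became 1 without healthy 1, 0 without healthy 2, 1 without MPO-AAGN 1, 1890 without MPO-AAGN 2 and 182 by DESeq2. All 13 named calls were lost without healthy 1 (adjusted p of 0.212 to 0.490), healthy 2 (0.168 to 0.433) or MPO-AAGN 1 (0.0712 to 0.237). List calls were lost for dissociation without healthy 2 (0.169) or MPO-AAGN 1 (0.108), for the unfolded protein response without healthy 2 (0.137) or MPO-AAGN 2 (0.0541), and for antioxidant genes without healthy 1 (0.185) or MPO-AAGN 1 (0.122).

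NK or innate lymphoid cells also had more Tigit, at 474 ± 30.2 against 40.9 ± 0.846 CPM (11.5-fold, log2 fold change 3.52 ± 0.25, adjusted p = 0.000139). A Tigit UMI was found in 10.1%, 7.60%, 65.1% and 61.7% of cells and, thinned, in 3.67%, 4.17%, 33% and 34.4%, at median depths of 2570, 2257, 3826.5 and 2071 UMIs. Of 5276 genes 41 rose and 92 fell, of which 1 and 68 lay below 0.1 times their level in the highest class. The proliferation genes Ube2c (5.51 ± 1.24) and Mki67 (3.16 ± 0.55) rose, as did Serpina3f and Pik3ip1 (2.39 ± 0.47), while Hsph1 (-2.08 ± 0.44), a heat shock protein, and Idi1 fell, and Ifng did not pass (-0.31 ± 0.22, 0.505). Cell cycle genes had 2 of 11 up, Ube2c and Mki67 (4 adjusted over the list alone, 1.87e-05), and unfolded protein response genes 2 of 18 down, Calr (-1.52 ± 0.24) and Pdia6 (7 adjusted over the list alone, 5.63e-05). Proximal tubule transport genes had 1 of 9 down, Lrp2 (5 adjusted over the list alone, 0.000145). For these 3 lists the adjusted p was 0.839 with an estimated correlation. Free proximal tubule RNA alone would give over 50% of the healthy level of Gatm (-4.05 ± 0.47), Lrp2, Gsta2 and Idh1, and proximal tubule genes were 1.85%, 1.91%, 0.292% and 1.09% of the class's UMIs. Antioxidant genes fell as a list with 1 of 15 up, Mt1 at 2.09 ± 0.37, far below its highest class (1 up and 6 down adjusted over the list alone, 0.00486, adjusted p = 0.906 with an estimated correlation). Ribosomal protein genes rose with 0 of 38 called (0 adjusted over the list alone, 0.00945, adjusted p = 0.913 with an estimated correlation). The 133 genes became 14 without healthy 1, 18 without healthy 2, 200 without MPO-AAGN 1, 974 without MPO-AAGN 2 and 50 by DESeq2. Of the named calls 12 of 14 were lost without healthy 1 (adjusted p of 0.0705 to 0.368), 11 of 13 without healthy 2 (0.0761 to 0.598) and 7 of 13 without MPO-AAGN 1 (0.0938 to 0.549), Tigit and Gatm in none of these. The transport (0.173), antioxidant (0.339) and ribosomal list calls (0.909, direction turned) ended without MPO-AAGN 1, the last also without healthy 2 (0.110).

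In the whole suspension, with all cells of a library summed, edgeR called 0 of 15026 genes; 2811 had an unadjusted p under 0.05, and DESeq2 called 947. The number was 0 without healthy 1, 0 without healthy 2, 2879 without MPO-AAGN 1 and 8435 without MPO-AAGN 2. Of the 24 genes of the panel fixed for this disease, 19 could be tested there, with log2 fold changes from -1.02 for Cxcl9 to 7.69 for Prtn3 and a lowest adjusted p of 0.234. Within classes, panel genes that passed were Spp1, Cxcl10 and Lcn2 of 4 tested in distal cells, Lcn2 of 7 in endothelial cells, and Prtn3, Lcn2 and, downwards, Cxcl9 of 17 in mononuclear phagocytes. In the proximal tubule they were Icam1, C3, Spp1 and Lcn2 of 7, those 4 all far below their highest class. Of 5 tested in NK, 9 in T and 2 in intercalated cells 0 passed by edgeR. Untested in any class, Havcr1, a marker of tubular injury, had 4, 7, 57 and 4 UMIs in all cells of healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2, and Il6 had 5, 22, 8 and 1.

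Some genes moved one way in several classes, chosen for this paragraph after their values were seen. Mt1, which binds metals, rose in 7 of 7 classes tested, but lay far below its highest class in proximal tubule, endothelial, T and NK cells. Free proximal tubule RNA alone would give up to 48.6% of its MPO-AAGN level in T and 33.9% in NK cells. Increases were called for Fkbp5 in 5 of 7 (in T and NK cells it did not pass), Ddit4 in 5 of 7 (not in proximal tubule or intercalated cells) and Pdk4 in 4 of 4, though free proximal tubule RNA alone would give 134% to 164% of its level in endothelial cells of MPO-AAGN and 64.7% to 93.6% in intercalated cells. Idi1 fell in 6 of 7 (not in mononuclear phagocytes), and free proximal tubule RNA alone would give 33% to 58.9% of its healthy level in endothelial, intercalated, T and NK cells. Over classes, 48 of 124 pairs of list and class passed, 31 up and 17 down, and in each the median, the mean and the test had the same sign. With an estimated correlation 0 of the 124 passed (lowest adjusted p = 0.839, lowest unadjusted p = 0.0103), and by fry, which tests whether a list's genes move one way on balance, 1 passed, inflammatory cytokines in endothelial cells (0.0484), and 0 of the 48. MHC class I (lowest adjusted p = 0.152), MHC class II (0.0639) and chemokine genes (0.438) passed in no class, and immunoglobulin constant genes were too rarely detected to test. For reference, on GRCm38 (mm10) Cyp4a14 (ENSMUSG00000028715) lies on chromosome 4 from 115486200 to 115496142 and Lrg1 (ENSMUSG00000037095) on 17 from 56119678 to 56122001. Fkbp5 (ENSMUSG00000024222) is on 17 from 28399094 to 28517527, Cxcl9 (ENSMUSG00000029417) on 5 from 92321347 to 92328079, Prtn3 (ENSMUSG00000057729) on 10 from 79874476 to 79883174 and Tigit (ENSMUSG00000071552) on 16 from 43648867 to 43664146.

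**Figure D3:**
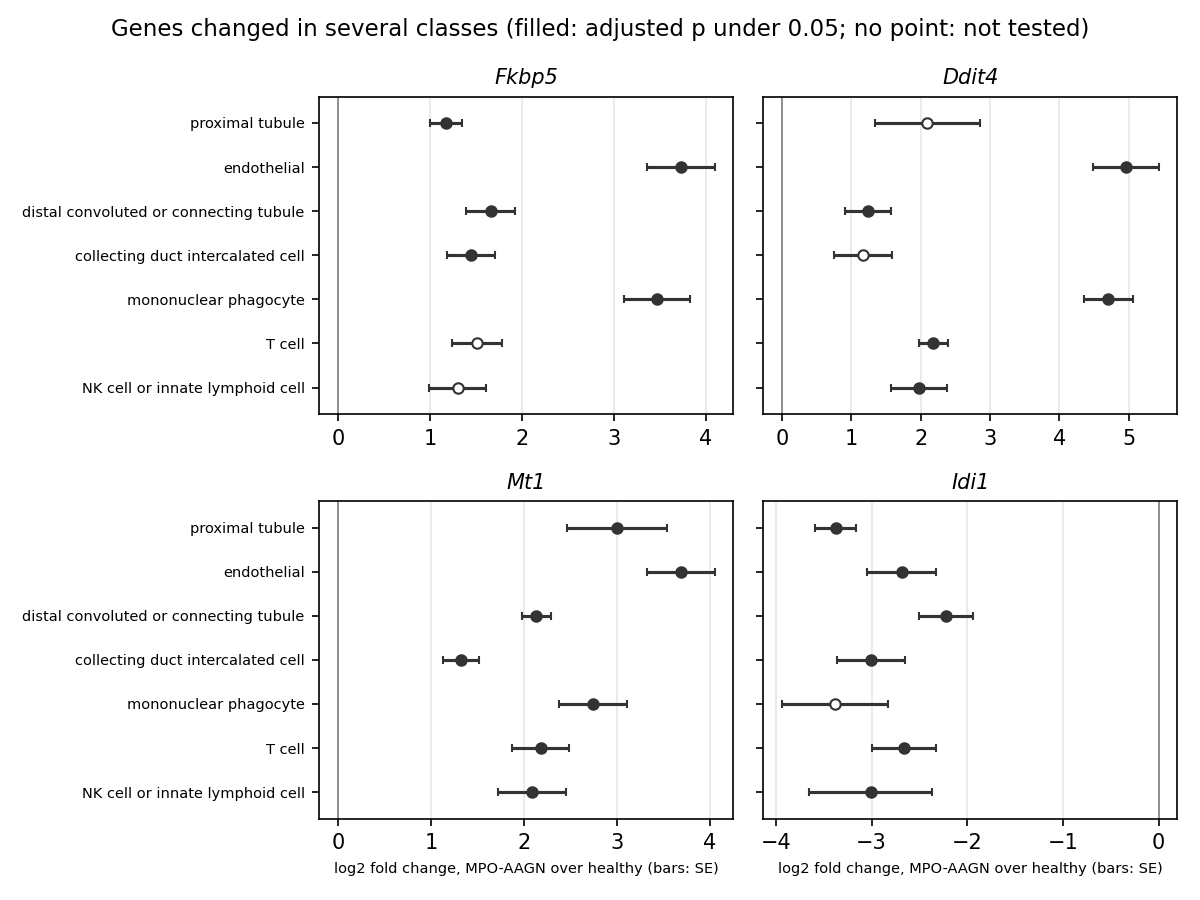
Log2 fold change, MPO-AAGN over healthy, of Fkbp5, Ddit4, Mt1 and Idi1 in the 7 tested classes, with bars of 1 SE, filled points where the adjusted p was under 0.05 and no point where the gene was not tested. Mt1 lies above 0 and is filled in 7 of 7 classes, though its level was far below its highest class in proximal tubule, endothelial, T and NK cells. Fkbp5 ranges up to 3.73 in endothelial cells, next to 1.17 in the proximal tubule.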

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

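For the number of genes called in proximal tubule cells, the tests with the guard against free RNA and with the immediate early list were chosen only after the result was seen, as was the test of Fkbp5 levels across classes.

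A direct test of the difference found 277 genes whose change differed between proximal tubule and endothelial cells. Log2 changes in the proximal tubule minus those in endothelial cells were -3.46 for Il15, 3.50 for Ucp2, -2.67 for Fkbp5, 1.99 for Egln3, -2.25 for Ppard, 1.84 for Acot2 and -2.31 for Bcl6. Among barcodes removed for having under 250 genes, those with over 50% of their UMIs from hemoglobin made up 0.943% of the deposited barcodes of MPO-AAGN 1 and 7.29% of those of MPO-AAGN 2, above 0.344% and 0.280% in healthy 1 and healthy 2.

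Transcripts of the proximal tubule were lower in T cells of both MPO-AAGN libraries, with a median log2 change of -1.97 over 149 genes, against -0.13 in proximal tubule cells. Doublets of a T cell and a tubule cell would put most of these UMIs in few cells, but the 5% of T cells with the most carried at most 25.9% of them in any library. Regulation by T cells of their own genes would not follow other cells, but the changes correlated across genes with those in distal tubule cells (rank correlation 0.694). Free RNA of proximal tubule cells in every droplet stays open as a candidate explanation, since the counts in T cells followed those in proximal tubule cells of the same library with a rank correlation over genes of 0.859 or more. The amount of free RNA was not measured, and whether disease or the preparation would have lowered it was not tested.

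Most genes were called in proximal tubule cells. Free RNA of other types stays open. Of the 2834 calls, 2345 were at genes near their highest class, at 0.1 times its level or more (2725 when only such genes were fitted and adjusted). Free RNA of the proximal tubule can reach that bound in other cells: in distal cells of healthy 1 it would give 256 CPM of Gatm, which stood at 1089 CPM in the proximal tubule. That example has the proximal tubule as the source and does not bear on free RNA of other classes entering proximal tubule cells. The latter was not estimated, so the guard cannot decide. A dissociation response of the whole suspension would raise the immediate early list in every class. The list's median change was 1.74 in the proximal tubule, 1.38 in distal, 0.52 in endothelial and 0.26 in intercalated cells. It was below 0 in 3 of the 7 classes (-0.24 in mononuclear phagocytes, -0.14 in NK and -0.27 in T cells). By the list test it rose in 4 classes and fell in 2, mononuclear phagocytes and T cells, which goes against a rise in every class. With an estimated correlation the lowest adjusted p was 0.839, so the explanation stays open. In the proximal tubule the list call ended when only genes near their highest class were kept (adjusted p = 0.834). Depth stays open too: with the same 94 cells and the same number of UMIs per library in all 7 classes, the median count over 10 draws was 215.5 in proximal tubule cells and 91.5 in the next class, under the 3-fold lead set beforehand as the mark of more than depth. An equal number of cells per library within each class could not test this, as classes stayed unequal, so this draw was added after the data were seen.

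Fkbp5 and Ddit4 were higher in MPO-AAGN in endothelial cells and mononuclear phagocytes. Free RNA of the proximal tubule is argued against in both of these classes. Alone it would give at most 4.35% of the MPO-AAGN level of Fkbp5 and 0.837% of that of Ddit4. Free RNA of other single classes was not estimated and stays open. Fkbp5 reached 0.1 times its highest level in 7 of 7 classes, but Ddit4 did not in intercalated (0.0895) and proximal tubule cells (0.0825). Free RNA of the proximal tubule can reach that bound in other cells, and whether that of another class can was not tested. Higher exposure to glucocorticoids is a candidate explanation that fits the other genes these hormones induce, which rose as a list in 6 of 7 classes (in T cells the adjusted p was 0.140), with medians of 1.40 in the proximal tubule and 1.27 in endothelial cells. Of its members 8 of 13 passed upwards in the proximal tubule, 6 of 12 in endothelial, 6 of 11 in distal, 2 of 10 in intercalated and 1 of 10 in NK cells and 0 of 11 in mononuclear phagocytes. With an estimated correlation the lowest adjusted p was 0.148, and Dusp1 is also on the immediate early list. Stress of disease, the immunisation and the adjuvant are not separated by the design, and hormone levels were not measured.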

How the results depend on the processing

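The draw of the same cells and UMIs in all 7 classes and the naming of subsets without their first-listed marker were chosen only after the result was seen. With 2 libraries per group a left-out library leaves 1 to stand for its group, and low depth in the small classes limits what can be called. Of the 182 named gene results that passed, none turned direction under any alternative run: of 3102 values 2809 kept both direction and side of the threshold and 293 no longer passed, and 84 results kept both in all. Every called gene had both libraries of a group above both of the other. Leaving out 1 library, which gave 722 of these values, could therefore hardly turn a direction. The other alternatives reuse the same 4 libraries, so the kept directions are no independent support. Of 59 that had not passed, 122 of 928 values passed and 32 turned. Of the 48 list calls 278 of 421 values kept, 135 ended and 8 turned. The 1 share call kept in 9 of 12 and the share call of type 1 dendritic cells among leukocytes in 4 of 13 values. RLE size factors and leaving out mitochondrially encoded genes moved no count by over 1.5 times. Where a value below changed, the cause was not tested unless named.

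Counts with 1 library left out ran from 817 to 13651 genes over all 7 classes (3938 with all), 382 to 5352 in proximal tubule, 119 to 2110 in endothelial, 215 to 1204 in distal, 0 to 461 in intercalated, 76 to 1660 in mononuclear phagocytes, 0 to 1890 in T, 14 to 974 in NK cells, 0 to 8435 in the whole suspension, 83 to 2187 in the interaction, 43 to 69 lists and 0 to 5 shares. DESeq2 gave 256 in distal, 91 in mononuclear phagocytes, 182 in T and 50 in NK cells and 947 in the whole suspension. No filter gave 8621 in all, with 4482, 779, 601, 510, 1065 and 380 in proximal tubule, endothelial, intercalated, mononuclear, T and NK cells. The guard gave 85 in mononuclear and 78 in NK cells, Scrublet's threshold 38 in intercalated, 59 in mononuclear and 230 in NK cells, and no doublet removal 246 in intercalated and 76 in mononuclear cells. A mitochondrial limit of 25% gave 215 in intercalated and 138 in T cells, and a minimum of 1000 UMIs 312 in distal, 48 in mononuclear and 126 in T cells and 2 shares. Resolution 0.5 gave 41 in mononuclear and 150 in T cells, and resolution 2 316 in distal, 38 in mononuclear and 168 in T cells and 0 shares. Libraries clustered separately gave 339 in distal and 3 in T cells, and equal cells 199 in intercalated, 112 in mononuclear and 59 in NK cells. The same cells and UMIs gave medians of 457 in all, 215.5 in proximal tubule, 58 in endothelial, 91.5 in distal, 21.5 in intercalated, 11 in T and 33 in NK cells, where fewer UMIs are tested by construction. Of the 48 list calls 0 held with an estimated correlation and 0 by fry, where the 1 list that passed was inflammatory cytokines in endothelial cells (adjusted p = 0.0484), not called by camera (0.0880).

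Replicate numbers do not pair the samples by the labels: differences between replicates correlated across genes at -0.124 in endothelial to 0.185 in proximal tubule cells. With the number as a block 6046 genes were called in all, 447 in endothelial, 903 in distal, 581 in intercalated, 135 in mononuclear, 303 in T and 261 in NK cells and 142 in the whole suspension. The block ended the call of type 1 dendritic cells among leukocytes (adjusted p = 0.228). Under the block Cd74 in intercalated cells was at -0.11 and Icam1 in NK cells at 0.0527.

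Values that turned direction, none of them called, had these lowest and highest log2 changes with 1 library left out: Cd274 in T cells -0.0639 and 0.22 and in the whole suspension -0.58 and 1.36; Cd74 in NK -0.88 and 3.01, T -0.0350 and 1.73, intercalated -2.58 and 1.74, distal cells -0.94 and 2.56 and the whole suspension -0.50 and 2.54; Csf1 in the whole suspension -0.65 and 0.84; Cxcl10 in the proximal tubule -1.22 and 0.47; Icam1 in NK cells -0.37 and 0.50 and mononuclear cells -0.60 and -0.07; Ifng in T cells -0.69 and 0.38; Nlrp3 in mononuclear cells -0.31 and 0.15; Spp1 in NK cells -1.56 and 1.36; Tnf in NK -0.41 and 0.28 and mononuclear cells -0.46 and 0.17. Libraries clustered separately gave -1.89 for Cd74 in T cells and 0.0272 for Icam1 and 0.0439 for Tnf in mononuclear cells. Nlrp3 there was 0.0212 at resolution 0.5 and 0.0326 at resolution 2. Icam1 in NK cells was 0.00673 with no filter, 0.46 with Scrublet's threshold, 0.57 at the 25% limit and 0.59 at 1000 UMIs.

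Shares that turned ran, with 1 library left out, from -0.0301 to 1.48 for NK, -0.56 to 0.30 for intercalated, -2.68 to 0.74 for principal, -0.84 to 0.24 for endothelial, -1.79 to 2.06 for erythroid, 0.09 to 1.13 for mesenchymal and -0.89 to 0.72 for thin limb cells, and 0.37 to 1.49 for non-classical monocytes of leukocytes. Without doublet removal principal cells were at 0.35, thin limb at 1.13 and non-classical monocytes at -0.13, and with Scrublet's threshold principal cells at 0.0549 and these monocytes at -0.35. Principal cells were at 0.15 at resolution 0.5 and 0.0423 at resolution 2, where thin limb was at 1.09; without proximal tubule cells in the total mesenchymal cells were at -0.0706. Lists that turned had these lowest and highest adjusted p with 1 library left out: cell cycle in mononuclear phagocytes 9.55e-07 and 0.909, hemoglobin there 1.03e-33 and 0.605, tubular injury there 0.00363 and 0.0725 (0.96 with the guard), dissociation in endothelial cells 3.58e-23 and 0.0953, fatty acid oxidation there 1.44e-20 and 0.468, proximal tubule transport in intercalated cells 2.90e-05 and 0.788, tubular injury there 4.40e-18 and 0.979, and ribosomal genes in NK cells 4.85e-06 and 0.909.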

Other observations

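The test of androgen action was chosen only after the result was seen.

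Lcn2, named here outside the rule for named genes and after its values were seen, was also high in classes too small to test. In thick ascending limb cells it stood at 0, 5.52, 3148 and 700.1 CPM in healthy 1, healthy 2, MPO-AAGN 1 and MPO-AAGN 2. In principal cells of the collecting duct it stood at 47.7, 43.3, 7222 and 818 CPM, the last from 20 UMIs in a class of 5 cells. What free RNA of neutrophils would give in these classes was not estimated. Il17a was detected in 0.279%, 0.163%, 8.43% and 1.04% of T cells and, thinned to 1000 UMIs, in 0.313%, 0.179%, 6.41% and 0.896%, against 0% of proximal tubule cells, where a count of 0 allows up to 0.0769%, 0.0523%, 0.313% and 0.110%, with median depths of 2720, 2446, 4124 and 1945 UMIs in T cells and 3733, 4522.5, 5254 and 3634 in proximal tubule cells. Immunoglobulin made up 0.0657%, 0.0189%, 0.0359% and 0.00316% of UMIs. Cluster 1 of the proximal tubule, with 66 cells, was led by interferon-induced genes.

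Idi1, which sterols repress, was lower in several classes. A hypothesis is lower sterol synthesis, under which the other genes of the pathway would fall together. As a list they fell in 5 of 7 classes, with median log2 changes of -1.18 in mononuclear phagocytes, -1.11 in endothelial cells, -1.09 in distal cells, -0.81 in T cells and -0.72 in intercalated cells, but not in the proximal tubule (adjusted p = 0.137) or NK cells (0.780), and the lowest adjusted p was 0.148 with an estimated correlation. Single members passed downwards for 5 of 19 in distal cells and 0 in the other 4 of these 5 classes. In the proximal tubule 3 of 20 passed downwards and 2 upwards. What lower free proximal tubule RNA would add to the fall of the list in other classes was not tested. Sterol levels were not measured.

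Odc1 and Hsd3b2, genes that androgens affect in mouse kidney, fell in proximal tubule cells, which led to the hypothesis of lower androgen action. The androgen-induced genes had a median log2 change of -0.163 with 5 of 11 higher and 6 lower, and the androgen-repressed genes, with 3 measured, a median of -0.291. Members went both ways and the test does not decide.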
